A study of Homo sapiens with 4 samples.

How the data were processed

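RNA was measured in Huh-7, a human hepatocellular carcinoma cell line, on 4 Affymetrix human gene expression arrays, 2 of untreated cells and 2 of cells treated with transforming growth factor beta (TGF-beta). Per the labels' protocols, the cells grew in Dulbecco's modified Eagle medium with 10% heat-inactivated bovine serum, were harvested 48 h after TGF-beta was added, and gave total RNA by TRIzol extraction that was labelled with biotin. The dose of TGF-beta is not given in the sources used here. The labels number the arrays 1 and 2 in each group and do not say that they come from separate cultures, so p-values measure only the spread between these samples, which may be technical.

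The deposited values are probe set intensities on a linear scale, 1 per probe set and array. The submitters' processing notes name the affy package, and the settings, background correction and summary method are not given in the sources used here. Between arrays the deposited intensities had nearly equal quartiles, so they were taken as already normalized and no further scaling was applied. The intensities were converted to log2 with no offset, and a fold change is the ratio of the groups' geometric means. Intensities below about the lower quartile have little room to fall, so folds of dim genes can be understated. Array data have no read depth, and the number of arrays limits the precision. With 4 arrays, moderation gave 7.41 degrees of freedom per gene, of which 5.41 came from the prior.

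Probe sets were named through the platform's annotation table, which can be old, and symbols were updated by Entrez gene number through a RefSeq table of assembly GRCh38.p14, used for names only. Of 22215 probe sets, 19724 name 1 gene, 568 name several and 1923 have no name there. A current symbol was found for 19707 of those that name 1 gene. Probe sets with several names or none were left out of the comparison. Each gene is represented by its brightest probe set over the 4 arrays, which left 12165 genes. No genome build is named for the values, so coordinates are not printed. A planned check of RNA quality from the control probe sets was not run, because 0 control probe sets were among the values used here.

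TGF-beta was compared with untreated cells with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes over all genes and Benjamini-Hochberg adjustment. A gene is called changed at an adjusted p under 0.05. Every adjusted p of a gene comes from this fit. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists, and again with the correlation estimated from the arrays and with fry. With an estimated correlation, camera uses only the few residual degrees of freedom of the 4 arrays, so it had little power over 32 lists. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

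The 32 lists were written before the data were examined. They cover TGF-beta signalling (TGF-beta/SMAD target genes, the ID family, receptors with SMADs and co-regulators, and ligands with antagonists) and cell shape (extracellular matrix, mesenchymal markers, epithelial junctions and keratins, and actin with focal adhesion). Hepatocyte lists cover plasma proteins, transcription factors, drug and bile acid metabolism, urea cycle and amino acid metabolism, and fetal liver markers. Metabolic lists cover cholesterol synthesis, fatty acid oxidation, fatty acid synthesis, glycolysis and hypoxia, and gluconeogenesis. Growth lists cover G1/S, G2/M, CDK inhibitors, cell death, WNT target genes, and WNT ligands and receptors. Stress and inflammation lists cover the acute phase response, NF-kB targets, the interferon response, the unfolded protein and amino acid response, and cytoplasmic ribosomal proteins. Lists of fibroblast, leukocyte and endothelial markers stand for other cell types. Some genes are in more than 1 list.

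The rule for named genes was also fixed before the data were examined. It takes the 12 largest changes in each direction among called genes whose arrays separate by group, up to 3 called members of each list, the member with the smallest p of a list with no call, and 9 genes named in advance. These include SMAD7, SKIL, PMEPA1, AFP, ALB, AXIN2, LEF1 and MYC, and the remaining gene is not reported here. AXIN2 was not analysed here because no probe set used names it. All other genes named were chosen after their values were seen.

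The procedure was tested on simulated data with 12165 genes and 2 arrays against 2, in 20 runs with 200 changed genes each. It recovered 12.3% of genes changed by 0.5 on the log2 scale, 90.8% of those changed by 1 and 98.6% of those changed by 1.5, and 4.50% of calls were false. A list of 36 genes shifted by 0.3 reached an unadjusted camera p under 0.05 in 20 of 20 runs and an unshifted list in 1. The simulated genes were independent, with variances drawn from the prior fitted to these data, so the rates may be too favourable for correlated genes. The shift of 0.3 is larger in size than the median of each of the 32 lists. The alternatives tried were a block for replicate number, each array left out in turn, quantile normalization or median centring on top of the deposited values, removal of dim genes, a variance trend with robust estimation, array weights, an offset of 32, other choices of probe set, other thresholds, and the other list tests.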

Results

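Huh-7 is a hepatocellular carcinoma line that keeps many products of the hepatocyte, the main cell type of the liver. The series concerns molecular subtypes of hepatocellular carcinoma, and these arrays address what TGF-beta, a cytokine that signals through SMAD proteins, does to transcript levels in such cells. There were 2 arrays of untreated cells and 2 of cells harvested 48 h after treatment, with 12165 genes measured on each. Median probe set intensities were 50.3 and 50.1 in untreated cells and 51.0 and 50.7 after TGF-beta, so the arrays had about equal overall brightness. ALB (albumin, the main plasma protein) and AFP (alpha-fetoprotein, the fetal counterpart of albumin) were among the bright transcripts, at mean intensities of 33922 and 24027 in untreated cells. Their log2 fold changes were 0.07 ± 0.10 (SE, n = 2 per group) and 0.06 ± 0.10, and neither was called. The other 2 probe sets of ALB gave -0.34 and 0.43, and the one used lay near the highest intensities of the arrays (37821 to 39036), where changes can be compressed. Over all genes the median absolute log2 difference was 0.128 between the untreated arrays, 0.115 between the TGF-beta arrays, and 0.147 to 0.167 between arrays of different groups.

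After TGF-beta, 149 genes changed at an adjusted p under 0.05, of which 80 rose and 69 fell. The genes that rose most were HABP2 (a hyaluronan-binding plasma protease), CYP3A7 (a cytochrome P450 of fetal liver) and CXCR4 (the receptor of the chemokine CXCL12). HABP2 rose 3.74-fold, from a log2 intensity of 7.11 ± 0.41 to 9.01 ± 0.04 (SD, n = 2 each), with an adjusted p of 0.0114. CYP3A7 rose 3.28-fold (adjusted p = 0.0123) and CXCR4 3.24-fold (adjusted p = 0.00684). The largest decrease was that of TXNIP (a thioredoxin-binding protein that restrains glucose uptake), which fell by 1.82 ± 0.16 on the log2 scale (SE), with an adjusted p of 0.0101. CSTA (cystatin A, a protease inhibitor) fell by 1.57 ± 0.12 and NUPR1 (a stress-induced nuclear protein) by 1.33 ± 0.11.

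**Figure D1:**
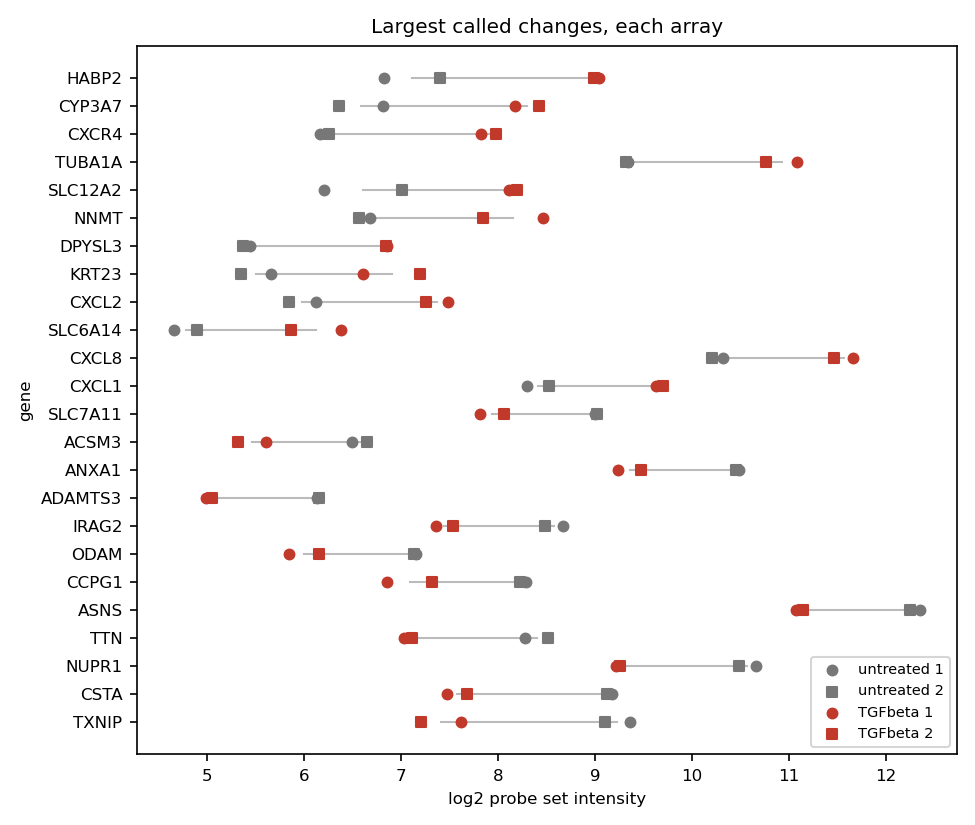
Log2 probe set intensity (horizontal axis) of the 12 genes with the largest called increase and the 12 with the largest called decrease (vertical axis), with 1 point per array, grey for untreated and red for TGF-beta, circles for array 1 and squares for array 2, and a line between the group means. In each gene both TGF-beta arrays lie on the same side of both untreated arrays, from HABP2 at a log2 fold change of 1.90 to TXNIP at -1.82.

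Other large increases were those of TUBA1A (an alpha-tubulin, 3.01-fold), SLC12A2 (the sodium-potassium-chloride cotransporter, 2.92-fold), NNMT (nicotinamide N-methyltransferase, 2.88-fold) and DPYSL3 (a cytoskeleton-associated protein, 2.71-fold). KRT23 (a type I keratin) rose 2.64-fold and SLC6A14 (an amino acid transporter) 2.54-fold. SLC6A14 was dim in untreated cells, at a mean log2 intensity of 4.78. Among decreases, TTN (titin) fell by 1.33 on the log2 scale, CCPG1 (a receptor for autophagy of the endoplasmic reticulum) by 1.17, ODAM by 1.14, IRAG2 by 1.13, ADAMTS3 (a procollagen N-proteinase) by 1.13, ANXA1 (annexin A1, a phospholipid-binding protein) by 1.11 and ACSM3 (a medium-chain acyl-CoA synthetase) by 1.11. Of the 149 genes, 36 changed at least 2-fold, 22 up and 14 down. The probe set used for CYP3A7 is of a kind that can match related transcripts. CYP3A4 and CYP3A5, its close relatives, had log2 fold changes of -0.04 ± 0.10 and 0.10 ± 0.12 (SE). Of the 149 genes, 59 had more than 1 probe set, and in 46 of these the other probe sets all had values in the same direction. Smaller values came from the other probe sets of CXCR4 (1.08 and 0.75), NNMT (0.67), DPYSL3 (0.43), CYP3A7 (1.26) and CCPG1 (-0.69 to -0.36).

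Both TGF-beta arrays lay on the same side of both untreated arrays in all 149 called genes. With 2 arrays per group, a gene whose arrays overlap cannot reach the threshold, so this separation follows from the calls and adds no support. Of all genes measured, 49.1% separated in this way, where chance gives 33.3%. At an unadjusted p under 0.05, 2184 genes passed. The count of calls depended on the arrays. It was 345 without untreated array 1, 523 without untreated array 2, 0 without TGF-beta array 1 (limma, 1326 genes at an unadjusted p under 0.05) and 0 without TGF-beta array 2 (1563 genes), while all 149 genes kept their direction in each of these fits. Leaving out 1 array cannot turn a gene whose arrays separate by group, so the kept directions add no support. Under quantile normalization 63 genes were called, 32 up and 31 down.

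Among NF-kB target genes, inducible genes of inflammation, 4 of 28 measured members rose, 1 fell and 23 did not pass. The 4 were CXCL2, CXCL8, CXCL1 and CCL20, chemokines that attract neutrophils or lymphocytes. CXCL2 rose 2.62-fold (adjusted p = 0.0123), CXCL8 2.47-fold (adjusted p = 0.0101), CXCL1 2.38-fold (adjusted p = 0.0114) and CCL20 by 0.62 on the log2 scale (adjusted p = 0.0489). VCAM1, an adhesion molecule for leukocytes, fell by 0.74 (adjusted p = 0.0387). The calls adjusted over the list alone were 8 higher and 2 lower. The list's median log2 fold change was 0.10 and camera did not place it past the threshold (adjusted p = 0.0524). The annotation lists 9 probe sets under CXCL8, and with the mean of all of them its log2 fold change was 0.28 and the call was lost. The only other bright one gave 1.37 ± 0.12 (SE), while the rest were dim (mean log2 intensities 4.43 to 5.34) and gave -0.21 to 0.21. The probe set used for CXCL2 can match related transcripts, and its close relatives CXCL1 and CXCL3 had log2 fold changes of 1.25 ± 0.12 and 0.13 ± 0.13 (SE), so a contribution from CXCL1 to the CXCL2 value was not excluded.

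Acute phase genes, which the liver induces in inflammation, had 2 calls among 24 measured members, CEBPD (a transcription factor of the C/EBP family) at 1.78-fold higher and SAA4 (a serum amyloid A protein) at 1.71-fold higher. The other probe sets of CEBPD, which were dim (mean log2 intensities 4.93 and 4.64), gave log2 fold changes of 0.22 and 0.11. In this list 5 rose and 1 fell when adjusted over the list alone, and the median was 0.06 (camera adjusted p = 0.267). In the interferon response list, IRF9 (the DNA-binding subunit of the interferon-activated factor ISGF3) rose 1.73-fold. LGALS3BP (a secreted galectin ligand), dim in untreated cells at a mean log2 intensity of 4.99, rose 1.76-fold. The other 38 of 40 did not pass, and adjusted over the list alone 2 rose and 4 fell. The interferon list had a median of -0.02 (camera adjusted p = 0.846), and the classical interferon-induced genes IFIT1 and IFIT3 had values of -0.45 and -0.50 with adjusted p of 0.106 and 0.0722.

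Genes of the unfolded protein and amino acid response were lower as a list in camera (adjusted p = 0.0103), a call lost with an adjusted p = 0.564 with an estimated correlation. Of 36 measured members 6 fell, 0 rose and 30 did not pass. The 6 were NUPR1, ASNS (asparagine synthetase), SLC7A11 (the cystine transporter), PHGDH and PSAT1 (enzymes of serine synthesis) and DDIT3 (a stress-induced transcription factor, CHOP). ASNS fell by 1.19 ± 0.11 on the log2 scale (SE, adjusted p = 0.0101), from 12.30 ± 0.07 to 11.11 ± 0.05 (SD, n = 2 each). SLC7A11 fell by 1.07, PHGDH by 0.81, PSAT1 by 0.70 and DDIT3 by 0.67. With p adjusted over the list alone, 11 fell and 1 rose, the latter SDF2L1, an endoplasmic reticulum protein, with a log2 fold change of 0.60. The list median was -0.10 and its mean -0.22. A group of 15 endoplasmic reticulum genes of the list was formed after the values were seen. It holds chaperones and folding enzymes, the degradation factors HERPUD1, SEL1L and EDEM1, and the transcription factor XBP1. The group had a median of 0.07, 10 positive values and 0 calls (3 higher and 0 lower at an unadjusted p under 0.05). HSPA5 (BiP) stood at 0.28 and HSP90B1 (GRP94) at -0.08.

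**Figure D2:**
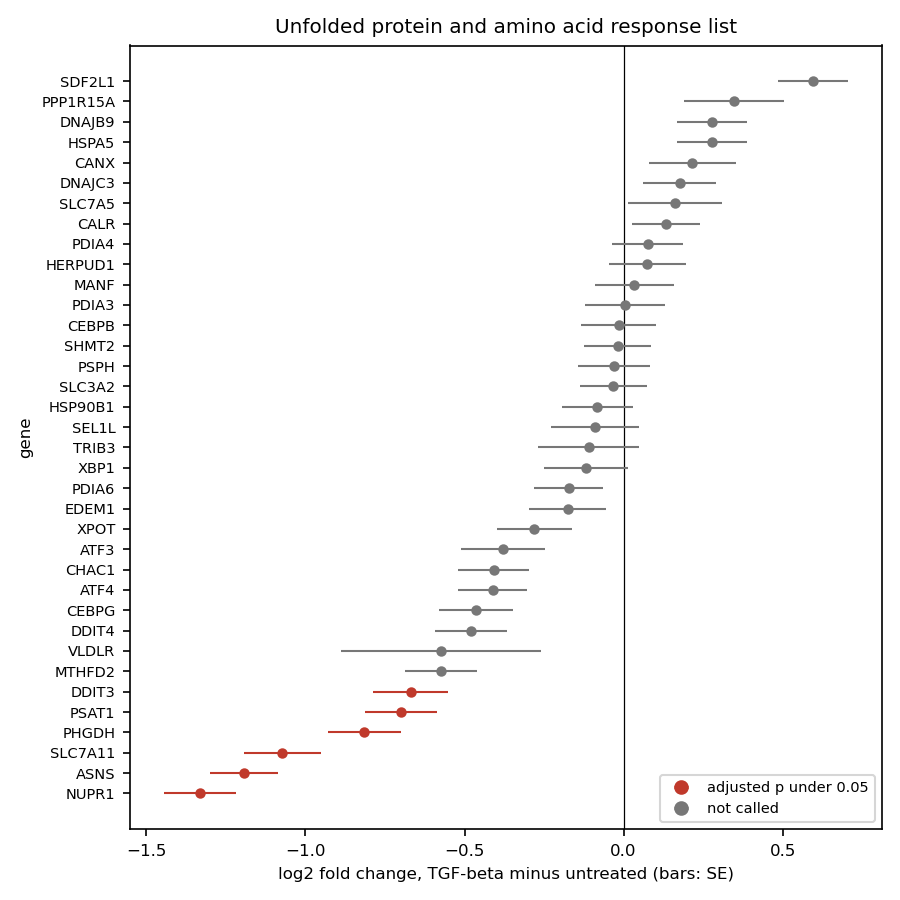
Log2 fold change, TGF-beta minus untreated (horizontal axis), of the 36 measured members of the unfolded protein and amino acid response list (vertical axis), with bars of 1 SE from the limma fit and red points for adjusted p under 0.05. The 6 called members lie between NUPR1 at -1.33 and DDIT3 at -0.67, and 12 of the 36 members lie above 0.

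Genes of actin and focal adhesion rose as a group by a small amount. The list median was 0.16, 28 of 36 measured members had a positive value, and camera gave an adjusted p of 0.00302, which became an adjusted p = 0.564 with an estimated correlation. Only RHOB (a small GTPase) was called, 1.74-fold higher with an adjusted p of 0.0256, and 35 members did not pass. When adjusted over the list alone, 6 rose and 0 fell. These were RHOB, ITGB5 (integrin beta 5), ACTN4 and ACTN1 (alpha-actinins), PDLIM1 and LASP1, with log2 fold changes of 0.37 to 0.80.

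**Figure D3:**
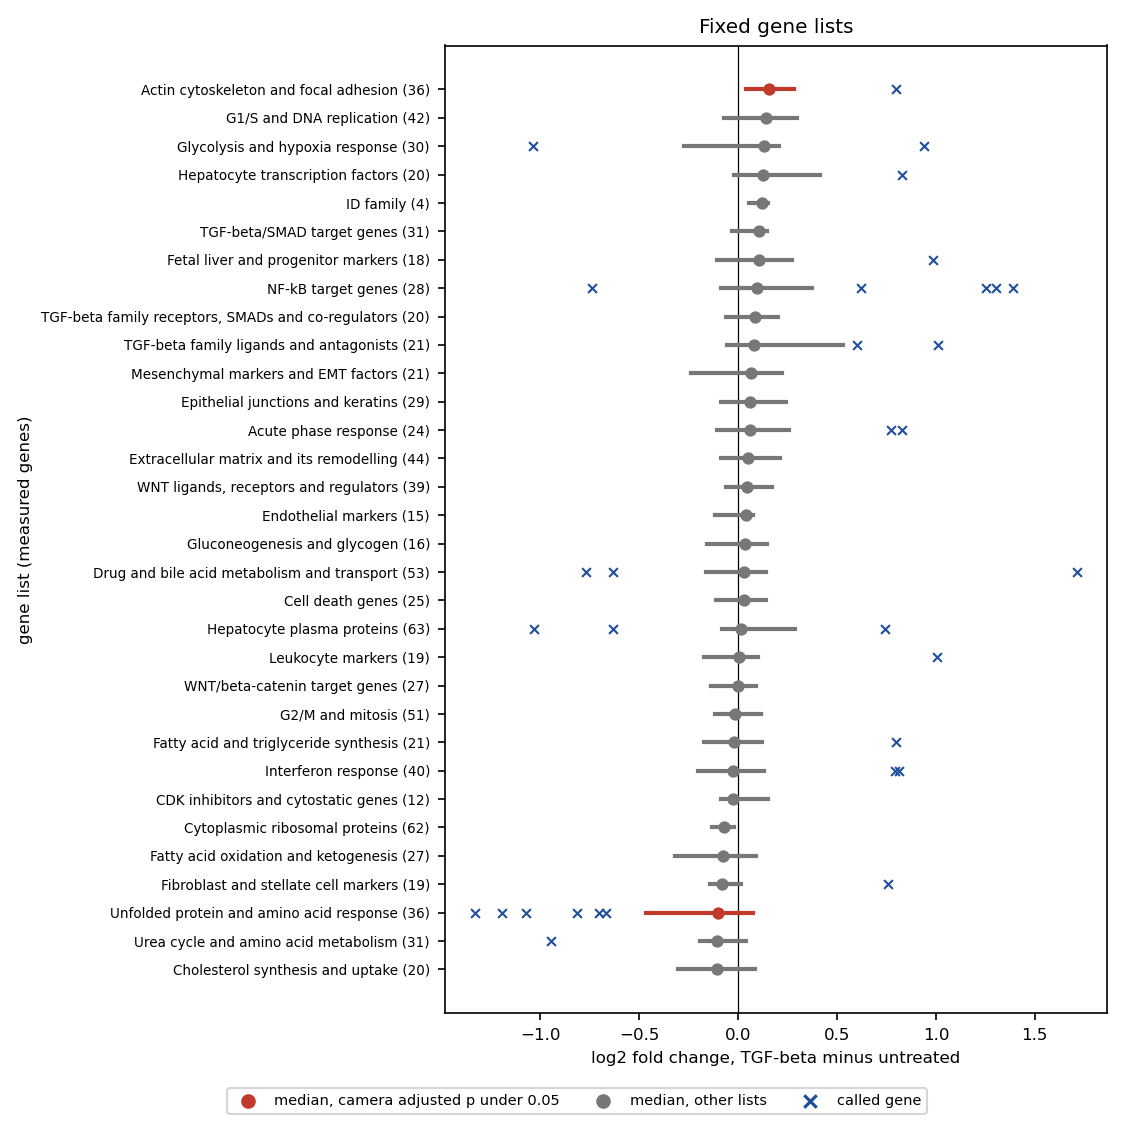
Median log2 fold change, TGF-beta minus untreated (horizontal axis), of each of the 32 gene lists (vertical axis, measured genes in parentheses), with bars from the lower to the upper quartile of the members and crosses for called genes. Red marks the 2 lists with a camera adjusted p under 0.05, actin and focal adhesion at 0.16 and the unfolded protein and amino acid response at -0.10.

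These were the 2 lists of 32 past the threshold. With an estimated correlation 0 lists passed (0 at an unadjusted p under 0.05), and with fry 0 passed (9 at an unadjusted p under 0.05, smallest adjusted p 0.0516). The estimated-correlation test has few degrees of freedom here, so its result does not separate correlation among genes from low power. The camera adjusted p of the other 30 lists lay between 0.0524 and 0.918.

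TGF-beta/SMAD target genes, textbook direct or early targets, had 0 calls among 31 measured members. At an unadjusted p under 0.05, 5 lay higher and 1 lower, and adjusted over the list alone 0 passed. Their median log2 fold change was 0.11, with 22 of 31 members positive and a camera adjusted p of 0.171. SMAD7 and SKIL, feedback inhibitors of the pathway, had log2 fold changes of -0.03 ± 0.13 and 0.06 ± 0.16 (SE). PMEPA1, another inhibitor, stood at -0.23 ± 0.12, and SPHK1 (sphingosine kinase), the member with the smallest p, at 0.49 (adjusted p = 0.0931). CCN2, a matricellular protein, stood at 0.12 and TGFBI at 0.13. In the ID family, inhibitors of DNA binding, 0 of 4 passed (0 at an unadjusted p under 0.05), with a median of 0.12 and ID3 at 0.16.

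Receptors, SMADs and co-regulators had 0 calls among 20 members (3 higher and 1 lower at an unadjusted p under 0.05) and a median of 0.09. The 2 that rose when adjusted over the list alone were ACVR1 (an activin and BMP receptor) at 0.57 and SMAD3 (a TGF-beta signal transducer) at 0.52. TGFBR1 and TGFBR2, the TGF-beta receptors, had values of -0.41 and 0.33 with adjusted p of 0.249 and 0.225. Among ligands and antagonists, 2 of 21 members rose, LEFTY2 (an inhibitor of NODAL signalling) 2.01-fold and GDF15 (a stress-induced family member) 1.52-fold. LEFTY2 was dim in untreated cells, at a mean log2 intensity of 5.07. The other probe set of GDF15, which was dim (mean log2 intensity 4.59), gave a log2 fold change of 0.09. Of these ligands 3 rose and 1 fell when adjusted over the list alone, and the median was 0.08 (camera adjusted p = 0.133).

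Extracellular matrix genes had 0 calls among 44 members (6 higher and 5 lower at an unadjusted p under 0.05, 0 adjusted over the list alone) and a median of 0.05. THBS1 (thrombospondin 1) had the smallest p in that list, at 0.73 ± 0.14 (SE, adjusted p = 0.0570). Its other 4 probe sets, all dimmer, gave 1.05 ± 0.12, 0.97 ± 0.18, 0.44 ± 0.12 and 0.17 ± 0.19 (SE). The lack of a call for THBS1 therefore holds for its brightest probe set only. FN1 (fibronectin) stood at 0.37 (adjusted p = 0.302). Mesenchymal markers and transcription factors of the epithelial-mesenchymal transition had 0 calls among 21 members, against 3 higher and 4 lower at an unadjusted p under 0.05. Adjusted over the list alone, 2 rose (SPARC and S100A4) and 3 fell (SNAI2, NT5E and TCF4), with SNAI2, a repressor of E-cadherin, at -0.55 (adjusted p = 0.0551). VIM (vimentin) stood at 0.22 and the median at 0.07. Epithelial junction and keratin genes had 0 calls among 29 members, 6 higher and 2 lower at an unadjusted p under 0.05, and a median of 0.06. Of these, adjusted over the list alone, EPCAM, an epithelial adhesion molecule, rose with a value of 0.56, and CDH17, a cadherin, fell with a value of -0.60. CDH1 (E-cadherin) stood at -0.24 with an adjusted p of 0.452.

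Of 63 measured hepatocyte plasma proteins, APOA1 (the main protein of high-density lipoprotein) rose 1.67-fold, KNG1 (kininogen) fell by 1.03 on the log2 scale, TTR (transthyretin) fell by 0.63, and 60 did not pass. The secreted proteins included 12 that rose and 3 that fell when adjusted over the list alone. The list median was 0.02 (camera adjusted p = 0.164). It turned to -0.003 under median centring of the arrays. Among hepatocyte transcription factors CEBPD was the 1 call of 20, and adjusted over the list alone 3 rose, the other two being NR0B2 (SHP, a repressor in bile acid signalling) at 0.67 and RXRA (a nuclear receptor partner) at 0.81. That list had a median of 0.13 (camera adjusted p = 0.0524).

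Of 53 genes of drug and bile acid metabolism, CYP3A7 rose, SULT2A1 (a sulfotransferase of steroids and bile acids) fell by 0.77, GSTA4 (a glutathione transferase) fell by 0.63, and 50 did not pass. The other probe set of SULT2A1 gave a smaller value, -0.23 ± 0.12 (SE). Equal numbers, 4 and 4, rose and fell when adjusted over the list alone, with a median of 0.03. In the urea cycle and amino acid list, CTH (cystathionine gamma-lyase, which makes cysteine) fell by 0.95 and 30 of 31 did not pass. Adjusted over the list alone, 3 fell, CTH, KYNU at -0.75 and CBS (the preceding enzyme of the same pathway) at -0.63, and the median was -0.10 (camera adjusted p = 0.133). Among fetal liver and progenitor markers ANPEP (aminopeptidase N) rose 1.98-fold, 17 of 18 did not pass, and EPCAM was the other of 2 higher when adjusted over the list alone. Their median was 0.10 (camera adjusted p = 0.267).

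Lists of lipid metabolism held 1 call, SREBF1 (a transcription factor of lipid synthesis). SREBF1 rose 1.74-fold, from a dim mean log2 intensity of 5.28 in untreated cells. It was the 1 call among 21 genes of fatty acid and triglyceride synthesis, of which 2 rose when adjusted over the list alone, with a median of -0.02 and a mean of 0.02. Cholesterol synthesis had 0 calls among 20 (2 higher and 6 lower at an unadjusted p under 0.05, 1 higher and 2 lower adjusted over the list alone) and a median of -0.11. HMGCS1, an early enzyme of that pathway, stood at -0.59 (adjusted p = 0.0517). Fatty acid oxidation had 0 calls among 27 (3 higher and 8 lower at an unadjusted p under 0.05, 1 higher and 4 lower adjusted over the list alone) and a median of -0.08, with ACOX2, a peroxisomal oxidase of branched chains, at -0.67 (adjusted p = 0.0541).

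In glycolysis and the hypoxia response PFKFB3 (which makes fructose 2,6-bisphosphate, an activator of glycolysis) rose 1.92-fold, STC2 (stanniocalcin 2) fell by 1.04, and 28 of 30 did not pass. The other probe set of STC2 gave -0.27 ± 0.17 (SE). The calls adjusted over the list alone were 2 higher and 2 lower, and the median was 0.13 (camera adjusted p = 0.791). Gluconeogenesis and glycogen genes had 0 calls among 16 (3 higher and 2 lower at an unadjusted p under 0.05, 1 higher and 2 lower adjusted over the list alone). Their median was 0.03 and their mean -0.003, with PYGL (liver glycogen phosphorylase) at -0.50.

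Genes of G1/S and DNA replication had 0 calls among 42 members (11 higher and 3 lower at an unadjusted p under 0.05, 0 adjusted over the list alone) and a median of 0.14 (camera adjusted p = 0.0524), with GINS1 (a replication helicase subunit) at 0.46. G2/M genes had 0 calls among 51 (8 higher and 5 lower at an unadjusted p under 0.05). Their median of -0.01, against a mean of 0.03, turned to 0.02 under quantile normalization. The 3 that rose when adjusted over the list alone were PLK1 (a mitotic kinase) at 0.71, CDC25B at 0.68 and CDC20 at 0.47. CDK inhibitors and cytostatic genes had 0 calls among 12 (1 higher and 1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone), a median of -0.03 and a mean of 0.02. In that list PLK2 stood at 0.34, CDKN1A (p21) at 0.22 and CDKN2B (p15) at 0.14. Cell death genes had 0 calls among 25 (3 higher and 2 lower at an unadjusted p under 0.05) and a median of 0.03. Adjusted over the list alone, BCL2L1 (BCL-XL, an inhibitor of apoptosis) rose with a value of 0.55, and PDCD4 and PMAIP1 (NOXA, a promoter of apoptosis) fell with values of -0.64 and -0.77. The other probe sets of PDCD4, all dimmer, gave 0.17, -0.36 and -0.38.

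WNT/beta-catenin target genes had 0 calls among 27 (3 higher and 2 lower at an unadjusted p under 0.05). Adjusted over the list alone, 2 rose, DKK1 (a secreted WNT inhibitor) at 0.56 and MYC (a transcription factor of growth) at 0.55, and OAT fell at -0.49. The list median was -0.0002, its mean 0.002, and it turned to 0.01 under quantile normalization. LEF1, a partner of beta-catenin, stood at 0.09 ± 0.10 (SE). WNT ligands, receptors and regulators had 0 calls among 39 (2 higher and 0 lower at an unadjusted p under 0.05, 0 adjusted over the list alone) and a median of 0.05, with DVL3 at 0.47.

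Cytoplasmic ribosomal proteins had 0 calls among 62 (1 higher and 2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone). Their values were small and mostly negative, with 55 of 62 below 0, a median of -0.07 and a camera adjusted p of 0.0524. RPL37A, the member with the smallest p, stood at 0.37. Markers of other cell types had 2 calls. CD14 (a receptor for lipopolysaccharide) was the 1 call of 19 leukocyte markers, rising from a log2 intensity of 6.24 to 7.24, and adjusted over the list alone 1 rose and 2 fell. The leukocyte median of 0.007, against a mean of -0.01, turned to -0.01 under median centring. PDGFRA (a receptor of platelet-derived growth factor) was the 1 call of 19 fibroblast and stellate cell markers at 1.69-fold higher, also when adjusted over the list alone. Its other probe set, which was dim (mean log2 intensity 4.51), gave a log2 fold change of -0.14. The fibroblast median was -0.08. Endothelial markers had 0 calls among 15 (0 higher and 3 lower at an unadjusted p under 0.05, 0 adjusted over the list alone), a median of 0.04, a mean of -0.03 and PECAM1 at -0.34.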

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

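Of the 1923 probe sets with no gene name in the annotation used, which the comparison left out, 9 passed an adjusted p under 0.05 when all probe sets were tested together, 5 higher and 4 lower after TGF-beta. In that test 174 of the 19724 probe sets that name 1 gene and 7 of the 568 that name several also passed. What the unnamed probe sets measure was not examined, and no explanation for them was tested.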

How the results depend on the processing

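All alternatives were chosen before the data were examined. The 149 called genes kept their direction wherever they were retested gene by gene. Because their arrays separate by group, only quantile normalization, median centring and the mean of probe sets could have turned them. Where a count moved the cause was not tested, except for stricter thresholds and for fewer arrays or genes, which change the test itself. The count of changed genes (higher, lower) was 63 (32, 31) with quantile normalization, 89 (53, 36) without the lowest 25% of genes, 92 (48, 44) without the lowest 50%, 51 (23, 28) with log2(value + 32), 632 (315, 317) with a variance trend, 3 (2, 1) at an adjusted p under 0.01 and 36 (22, 14) with a 2-fold minimum. Without moderation of the variance it was 0 (0, 0), with 1326 genes at an unadjusted p under 0.05. Median centring gave 105 lower genes. Leaving out each array gave 0 to 523 changed, 0 to 324 higher and 0 to 199 lower, the lone array being assumed to vary like the other group. Array weights, all probe sets, the mean of probe sets, and removal of probe sets of the shared kinds stayed within 1.5 times of 149, but of the 162 genes called with the mean of probe sets only 114 were among the 149. The replicate numbers do not pair the arrays (correlation of deviations 0.00966), and with a replicate block 1229 genes were called (686, 543) and 5 lists passed. The lists passing were 6 with median centring, 7 with a variance trend, 4 with log2(value + 32), 0 with an estimated correlation and 0 with fry. The 2 lists past the threshold kept it in 15 of 17 alternatives each, the last named pair being the exceptions. The planned RNA quality check was not run.

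Lists that changed sign were called in neither setting. Quantile normalization gave 0.0189 for G2/M and 0.0125 for WNT targets, and median centring -0.00278 for plasma proteins and -0.0127 for leukocyte markers. Without the lowest 25% of genes drug metabolism stood at -0.0521, gluconeogenesis at -0.0800, leukocyte at -0.0899 and endothelial markers at -0.183. Without the lowest 50%, drug metabolism stood at -0.0496, CDK inhibitors at 0.0542, WNT targets at 0.0426, interferon at 0.00103 and fibroblast markers at 0.0743. WNT targets stood at 0.000453 with log2(value + 32) and at 0.00466 with the mean of probe sets, which put CDK inhibitors at 0.0272. Without probe sets of the shared kinds, TGF-beta ligands stood at -0.0654, mesenchymal markers at -0.0485, drug metabolism at -0.0131, glycolysis at -0.185, gluconeogenesis at -0.0443 and fibroblast markers at 0.0107. With genes of 1 list only, WNT targets stood at 0.0148 and acute phase genes at -0.112. With each array left out, the ranges were -0.0436 to 0.142 for acute phase, -0.0535 to 0.0558 for CDK inhibitors, -0.0593 to 0.0371 for cell death, -0.00635 to 0.0257 for endothelial markers, -0.0461 to 0.0447 for G2/M, -0.0471 to 0.0353 for gluconeogenesis, -0.0447 to 0.00695 for interferon, -0.0794 to -0.00250 for leukocyte markers, -0.0228 to 0.0955 for mesenchymal markers and -0.00227 to 0.0570 for WNT targets. SKIL ranged from -0.17 to 0.29 and SMAD7 from -0.17 to 0.12. Over named genes and settings, 724 values stayed on their side of the threshold, 48 passed it, 136 lost it and 3 turned. Over lists 474 stayed, 18 passed, 4 lost it and 45 turned. Among named genes, the calls lost (gained) were 12 (0) with quantile normalization, 19 (0) with log2(value + 32) and 5 (4) with the mean of probe sets. Dim genes limit the arrays: the lower quartile of intensity was 28.8 to 29.2, near the lowest values of 15.2 to 16.2.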

Other observations

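The tests of probe sets of the shared kinds, the endoplasmic reticulum genes, array swaps, exchanged group names and other splits of the arrays were chosen after their results, or values close to them, had been seen. The lists tested here were written after the comparison. Immediate-early genes, which growth factor signals induce within minutes to hours, had mostly positive values after TGF-beta. The list had a camera p of 4.88e-05, and p = 0.0687 with an estimated correlation. Its place past the threshold therefore depends on the form of the test, in which both the correlation and the degrees of freedom differ. Of 20 measured, 16 had a positive value and the median log2 fold change was 0.327 (bootstrap interval 0.0503 to 0.448). PHLDA1 rose 1.68-fold and was the 1 call (limma adjusted p = 0.0403). The phosphatases DUSP4, DUSP6 and DUSP5, which switch off MAP kinases, had log2 fold changes of 0.90, 0.80 and 0.65 with adjusted p of 0.0631, 0.0558 and 0.0549. EGR1 and FOS, early transcription factors of the same class, stood at 0.01 and -0.22. The list was written after the higher chemokine genes were seen. A growth factor or stress signal still active at 48 h is a hypothesis for both, and it was not tested.

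Genes of ribosome biogenesis, the nucleolar factors that process ribosomal RNA and assemble ribosomal subunits, also had mostly positive values, with a camera p of 1.72e-07 that became p = 0.137 with an estimated correlation. Of 29 measured, 26 had a positive value, the median was 0.206 (bootstrap interval 0.124 to 0.393), and RRP12 was the 1 call at 1.66-fold (limma adjusted p = 0.0403). NOP2, RRS1 and GRWD1 stood at 0.55, 0.60 and 0.53. CCDC86, a nucleolar protein chosen after its value was seen, rose 1.95-fold (adjusted p = 0.0235), while the list of cytoplasmic ribosomal proteins had a median of -0.07. MYC drives many of these genes and stood at 0.55 (adjusted p = 0.0558), so higher MYC activity is a hypothesis. Protein levels and MYC binding were not analysed here.

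The lower amino acid response genes were weighed against technical explanations. ATF4 is the transcription factor that induces ASNS, PSAT1, SLC7A11 and many tRNA synthetases when amino acids run short, and its own value was -0.41 (adjusted p = 0.109). Of 12 ATF4-linked synthetases, none of them in the tested list, 11 lay below 0 with a median of -0.269, against 0.0655 for 6 other cytoplasmic synthetases (difference -0.334, permutation p = 0.00998 over genes, which are not independent), and SARS1 was called, at 1.56-fold lower. Cross-matching probe sets as the whole cause are argued against by the list's camera adjusted p of 0.00405 without probe sets of the shared kinds (0.000429 to 0.564 over all 17 alternatives, past the threshold in 15), but ASNS, NUPR1 and PSAT1 rest on such probe sets, and the only other probe sets of called members, both of SLC7A11, had a median of -0.695. The 15 endoplasmic reticulum genes, chaperones and other factors, had a median of 0.0736 (interval -0.0899 to 0.216), so as a group they were not clearly lower. This group was formed after the values were seen and holds none of the called members, with DDIT3 outside it. It therefore cannot decide whether the endoplasmic reticulum stress response as a whole was lower. A lower ATF4 response may therefore be followed up, for example from a difference in medium supply or cell density between dishes or from TGF-beta itself. These sources were not tested.

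TGF-beta/SMAD targets had no calls although the cells were treated. Too little signal to measure them is argued against only for the 17 targets brighter than the median gene, whose median was 0.0999 (interval -0.0313 to 0.120). For the dimmer targets it stays open. A swap of an array between the groups is argued against because 4 of the 4 arrays correlated best with their own replicate. This holds only if the treatment, and not the dish or the processing, is the main difference between the arrays, which was not tested. Exchanged group names cannot be told apart from correct ones, because the target list reached only a camera p of 0.0534, on the side of the labels. A weak response of these cells, a response that had passed by 48 h, or a low dose stay open and were not tested. In the simulation only 12.3% of genes changed by 0.5 on the log2 scale were recovered, against 90.8% of those changed by 1. The lack of calls therefore does not show a lack of response. For the 17 brighter targets, the lack of calls and the interval of their median argue against a typical rise of 1.

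The count of changed genes was set against the other ways to divide the 4 arrays into pairs. There are 3 such splits, too few for a share under 0.05. The real split gave 149 genes and 1 of the 3 splits gave as many, the highest other giving 0 (limma, 208 and 206 genes at an unadjusted p under 0.05 in the others against 2184). In the other splits any difference between the groups enters the residual spread, which lowers their counts. They are therefore no measure of the calls that would arise without a group difference, and no conclusion is drawn from them.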
